A study of Homo sapiens with 10 samples.

How the data were processed

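NB4 is a human acute promyelocytic leukemia line that carries the PML-RARA fusion, and KDM5A is a demethylase of lysine 4 of histone H3. KDM5A was disrupted with CRISPR-Cas9 and compared with scramble controls by RNA sequencing, with 2 scramble and 2 knockout libraries. Chromatin immunoprecipitation with sequencing (ChIP-seq) gave 1 library each of H3K4me2 and H3K4me3 in scramble and in knockout cells, and 1 library of KDM5A in wild-type cells. An input library of wild-type cells was not used here. Groups were taken from the sample titles. The guides described in the labels as controls target GFP, while the samples are called scramble, and the text follows the sample names. Nothing in the labels says that the RNA libraries came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

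The RNA table holds log2 expression values for 4 libraries. Per the file headers, the authors counted tags in exons on both strands with HOMER against hg19, kept 1 transcript per gene, applied no adjustment at that step, and then ran the HOMER step for differential expression with 2 scramble and 2 knockout libraries. The submitters' processing notes also name STAR, DESeq2, Trim Galore, Bowtie and MACS2, without versions. The values are not counts: they are not whole, no total per library matches the tag totals in the header, and genes with few tags lie close together in all libraries, as a regularized log2 transform gives. Which transform the authors applied is not given in the sources used here. Such values understate the fold changes of genes with few tags. Genes with higher values also had smaller fold changes here than the authors' own. MT2A had a log2 fold change of 2.79 here and 4.70 by the authors, and KDM5A -0.49 and -0.75. The same table holds the authors' log2 fold change, p-value and adjusted p-value per gene, per the file headers. The sign of their fold change was checked against the library columns (Spearman rho 0.817 across genes with the difference of the group means, higher meaning higher in knockout). The tag totals in the header were 46.3 M (46278992) and 30.4 M for the scramble libraries and 5.53 M and 78.2 M for the knockout libraries that the header calls KO1 and KO3. The sample titles number the knockouts 1 and 2, so KO3 is known only as a knockout, and the scramble columns could not be tied to a replicate number. The scramble libraries are therefore named by their tag totals.

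The peak lists of the 5 ChIP-seq libraries give for each peak a fold enrichment and the −log10 of p and q, as the authors' peak caller wrote them, in the narrowPeak layout of MACS2. A further deposited list holds regions of H3K4me2 in knockout over scramble, with a score of 10 times the negative log10 of p (lowest value 50.0), a fold enrichment and a false discovery rate of up to 2.04%. Its layout is that of an earlier MACS version and it has no header. Peaks were called on single libraries, on hg19 per the submitters' processing notes. Whether an input library served as control is not given in the sources used here. All positions are hg19, 1-based. The fold enrichments are the authors' and were used to rank or filter peaks within a list and, with p, to solve the background rate of the peak caller.

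The planned test for the RNA was a count model, with limma on log2(value + 1) if the columns were not counts. Because the values are already on a log2 scale, no pseudocount was added and limma 3.58.1 with a mean-variance trend was run on the deposited log2 values in R 4.3.3, two-sided, with Benjamini-Hochberg adjustment. DESeq2 and edgeR could not be run because the values are not counts, so the intended refits with these tools were left out. Genes entered at a mean value of at least 3.32, the log2 of 10, the minimum count of the planned model's filter. This minimum was settled after the number of calls at several minimums had been seen. Of 27945 genes in the table, 2551 were listed at 0 in all libraries and 12816 were tested. No symbol appeared more than once. Gene lists were tested with camera at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the lists, then with an estimated correlation. Fry was also run, which tests a list against no change and not against other genes. List medians were also placed among 10000 random lists matched on mean expression in 20 bins, and, as an addition, on chromosome and expression together. A random-list p compares the median of a set with these lists. It draws genes and not libraries, so it carries no spread between libraries and treats genes as independent. Lists with fewer than 5 tested members were not tested.

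Peaks counted as shared when they overlapped by at least 1 bp (bedtools 2.31.1). A peak within 1 kb of a transcription start site (TSS) in the RNA table was assigned to that gene, and a region of knockout over scramble within 5 kb. Fisher's exact tests were run in scipy 1.17.1, two-sided, and a Mantel-Haenszel odds ratio over 5 strata of knockout peak width in statsmodels 0.14.6. A further background was the merged H3K4me2 peaks of both libraries. Intervals of shares are exact binomial 95% intervals and cover counting error only. With 1 library per condition, the ChIP-seq comparisons have no replicate check, and peaks and genes are not replicates. Sets of genes linked to peaks were tested with camera, adjusted over the 3 sets. That adjustment was chosen after the unadjusted values had been seen. The background rate of the peak caller was sought for each peak from its fold enrichment and p, within a tolerance of 0.0002 on the log10 scale. It was solved for 100.0% of H3K4me2 peaks in both libraries but for 0 of 1947 KDM5A peaks. For H3K4me3 it was solved for 91.7% of scramble and 98.3% of knockout peaks.

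The gene lists, the statistical designs, the rule for named genes and most alternatives were fixed before the data were examined. The rule took KDM5A, then the genes past an adjusted p of 0.05 and of at least 1 CPM with both knockout libraries on the same side of both scramble libraries, with the 10 largest rises and the 10 largest falls. Genes on the Y chromosome and XIST were left out. The rule also took up to 4 members of each list past that threshold, or, where a list had none, its 2 members with the smallest p as values only. For ChIP-seq it took the 5 strongest KDM5A peaks at a TSS, the 10 strongest gained H3K4me2 regions near a TSS, and called genes with both. Some items that the rule took are not reported here. Alternatives covered the filter, leaving out each RNA library, thresholds, set tests, windows, peak thresholds, overlap rules and backgrounds. Median centring, quantile normalization, no trend, array weights, a minimum mean of 7, a library score as covariate and the tests of lists against peaks were added later. The library score is each library's position on the gene axis that best explains the differences between replicates in these same values. As a covariate it takes out the main spread between replicates by construction, so p-values with it can be too small and are no independent check. Tags were counted without regard to strand, so overlapping and antisense genes cannot be told apart, and members of the metallothionein, DEFA1 and NCF1 families can share tags with near-identical copies.

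The steps were tested on simulated data. With 200 of 12816 genes changed in the RNA comparison, a log2 change of 1 was recovered for 15.5% and a log2 change of 2 for 90.1% of changed genes, with 6.65 false calls per run. Lists of 30 genes shifted by 0.5 passed camera in 20 of 20 runs, and unshifted lists in 0. The simulated noise was independent between genes and held no axis shared by genes, unlike the real libraries. These rates therefore do not carry over to lists of correlated genes or to shorter lists. The background rate was recovered for 100.0% of 500 simulated peaks.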

Results

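The RNA of KDM5A-knockout and scramble NB4 cells was compared in 2 libraries per group, to ask which genes respond to loss of this H3K4 demethylase in cells driven by PML-RARA. ChIP-seq peak lists of H3K4me2 and H3K4me3 in both conditions and of KDM5A in wild-type cells, with 1 library each, addressed where the marks and the enzyme lie. The RNA libraries differed in depth, with 46.3 M and 30.4 M tags in scramble, 5.53 M in knockout KO1 and 78.2 M in knockout KO3. Expression is given as the deposited log2 value, mean ± SD over 2 libraries, and fold changes are knockout minus scramble on that scale.

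KDM5A (NM_001042603, chromosome 12, 389223 to 498621, minus strand) was the targeted gene. Its RNA was 9.74 ± 0.19 in scramble and 9.25 ± 0.38 in knockout (SD, n = 2), a log2 fold change of -0.49 (SE 0.38). Both knockout libraries, at 8.98 in KO1 and 9.52 in KO3, lay below both scramble libraries, at 9.87 and 9.61, but the difference did not pass the test (limma adjusted p = 0.874). Without KO1 the log2 fold change was -0.22 and without KO3 -0.76. The authors' deposited table gives a log2 fold change of -0.75 with an adjusted p of 0.928. A frameshift made by CRISPR-Cas9 need not lower a transcript, so this value neither proves nor excludes the edit.

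MT2A (NM_005953, chromosome 16, 56642445 to 56643409, plus strand), a metallothionein that binds zinc and copper, rose in the knockout. Its level was 8.59 ± 0.47 in scramble and 11.38 ± 0.49 in knockout (SD, n = 2), with 8.92 and 8.25 in the scramble libraries, 11.73 in KO1 and 11.04 in KO3. The log2 fold change was 2.79 (SE 0.39, limma adjusted p = 0.00883). MT2A was the 1 gene of 12816 that passed the threshold, and 863 genes had an unadjusted p under 0.05, 793 of them higher in knockout and 70 lower. The authors' deposited table calls 13 genes at an adjusted p under 0.05, all higher in knockout, with MT2A at a log2 fold change of 4.70. Among the others, named after their values were seen, are the cytoskeletal linker PLEC, the peroxidase GPX1, the metalloproteinase MMP17, the fatty acid synthase FASN and the receptor NOTCH1. In the limma fit these had log2 fold changes of 2.21 for PLEC, 2.09 for GPX1, 2.02 for MMP17, 1.91 for FASN and 1.76 for NOTCH1, with adjusted p from 0.0904 to 0.243. All 13 had both knockout libraries above both scramble libraries. They were called higher from these same libraries, so this order is no independent check. Over all tested genes, 2000 (15.6%) had both knockout libraries above both scramble libraries and 2506 (19.6%) had both below, where chance gives 16.7% each way. The genes with an unadjusted p under 0.05 also depended on single libraries. They numbered 2318 higher and 379 lower without the scramble library of 46.3 M tags, 214 and 101 without that of 30.4 M, 213 and 3 without KO1 and 681 and 236 without KO3. With the library score as covariate they were 300 and 137. The number of called genes depended on single libraries as well: it was 1260 (1238 higher) without the scramble library of 46.3 M tags, 6 without that of 30.4 M, 0 without KO1 and 50 without KO3. With each library centred on its median, 88 genes were called, 82 higher and 6 lower, and MT2A lost its call without KO1, without a filter and without a mean-variance trend.

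**Figure D1:**
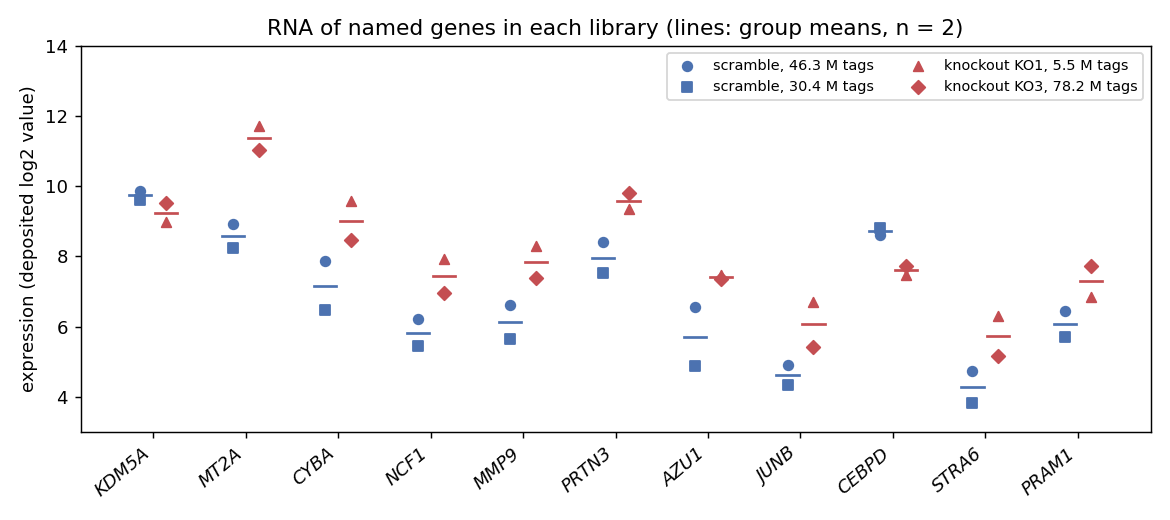
Deposited log2 expression values of named genes in each RNA library, with scramble libraries in blue and knockout libraries in red and a line at each group mean (n = 2). MT2A lies at 11.73 and 11.04 in the knockout libraries against 8.92 and 8.25 in scramble, while KDM5A lies at 8.98 and 9.52 against 9.87 and 9.61.

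The libraries also differed along chromosomes. Genes on chromosome 19, which is gene-dense and GC-rich, had a median log2 fold change of 0.44, those on chromosome 22 of 0.30 and those on chromosome 16 of 0.25. Genes on chromosomes 13, 4 and 18 had medians of -0.27, -0.25 and -0.24. The difference between the scramble libraries (46.3 minus 30.4 M tags) had a median of 0.50 on chromosomes 16, 17, 19, 20 and 22 and of -0.13 on chromosomes 3, 4, 5, 6, 13, 18 and X. The first principal component held 71.4% of the variance and set the scramble library of 30.4 M tags (score 57.7) against KO1 (score -42.3), with the remaining libraries at -8.10 and -7.25.

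**Figure D2:**
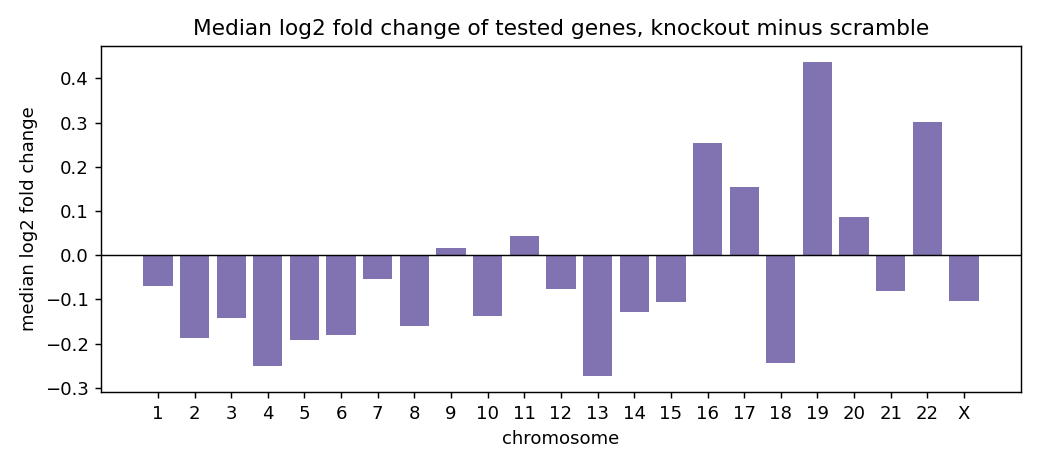
Median log2 fold change (knockout minus scramble, deposited log2 values) of the tested genes on each chromosome. The bars rise to 0.44 on chromosome 19 and reach -0.27 on chromosome 13.

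Genes of the NADPH oxidase and genes that respond to retinoic acid or PML-RARA were higher in knockout as lists by camera with its preset correlation, but not with an estimated correlation (adjusted p = 0.961 with an estimated correlation for both). The NADPH oxidase list, which encodes the superoxide-producing enzyme of phagocytes, had a median log2 fold change of 0.45 over 6 members (camera adjusted p = 0.0254), at percentile 96.5 of random lists of equal expression and 86.3 when these were also matched on chromosome. CYBA, its membrane subunit, was 7.17 ± 0.99 in scramble and 9.02 ± 0.79 in knockout (SD, n = 2), and NCF1, a cytosolic subunit with near-identical pseudogenes, was 5.83 ± 0.56 and 7.44 ± 0.70. The retinoic acid and PML-RARA list had a median of 0.37 over 20 members (camera adjusted p = 0.0254), at percentile 99.02 of random lists of equal expression, with 7 members above in both knockout libraries and 1 below. In it, STRA6, a retinol transporter, had a log2 fold change of 1.45 (SE 0.42), and PRAM1, an adaptor named for its control by PML-RARA, of 1.21 (SE 0.46). No member of either list passed the test over all genes, and adjusted over the list alone 2 of the NADPH oxidase list (CYBA and NCF1) and 0 of the retinoic acid list did. The medians of both lists moved with single libraries: the NADPH oxidase median was 1.05 without the scramble library of 46.3 M tags, 0.05 without that of 30.4 M and 0.26 without KO1, and the retinoic acid median was 0.60, 0.15 and 0.30, and 0.62 without KO3. Fry, which tests a list against no change and not against other genes, gave an adjusted p of 0.986 for both. Neither camera call held without KO1 (camera adjusted p = 0.216 for both) or with a library score as covariate (0.157 for both). The call of the retinoic acid list also ended under quantile normalization (median 0.19, camera adjusted p = 0.0758) and without a filter (median 0.073, camera adjusted p = 0.171). It ended too at a minimum mean of 7 (median 0.052, camera adjusted p = 0.395) and without the scramble library of 30.4 M tags. With the covariate the retinoic acid median was 0.17. The call of the NADPH oxidase list ended without a filter (camera adjusted p = 0.0852). Over the camera alternatives the adjusted p of both ranged from 0.00993 to 0.961.

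Granule genes, which mark stages of neutrophil maturation, did not pass as lists. In the primary granule list (14 tested, median -0.33, camera adjusted p = 0.837), PRTN3 had a log2 fold change of 1.61 (SE 0.42), AZU1 of 1.70 (SE 0.50) and PRSS57 of 1.59 (SE 0.52). These serine proteases or their inactive relatives lie on chromosome 19, and all 3 passed when adjusted over the list alone, though none did over all genes. The remaining 11 had values from -0.78 for MS4A3 to 0.30 for CFD, and the list median lay at percentile 0.73 of random lists of equal expression. In the secondary and tertiary granule list (8 tested, median 0.39, camera adjusted p = 0.0760), the gelatinase MMP9 was 6.13 ± 0.69 in scramble and 7.84 ± 0.64 in knockout (SD, n = 2) and was the 1 member that passed adjusted over the list alone, and MMP25 had a log2 fold change of 1.02. The median of the primary granule list was 0.19 without the scramble library of 46.3 M tags (adjusted p = 0.189) and -0.77 without that of 30.4 M (0.00198), where it passed, and it also passed with the library score as covariate (0.00329; range over the camera alternatives 0.00198 to 0.978). The secondary and tertiary granule list passed without the scramble library of 46.3 M tags (adjusted p = 0.0473) and without KO3 (0.0249; range 0.0249 to 0.961). Its median was 0.70 without the scramble library of 46.3 M tags and 0.0021 without that of 30.4 M (0.172), 0.16 under quantile normalization (0.183) and 0.081 with the covariate (0.191).

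Myeloid transcription factors had a median of 0.37 over 23 members (camera adjusted p = 0.155), at percentile 99.95 of random lists of equal expression. The median was 0.11 without the scramble library of 30.4 M tags (adjusted p = 0.234) and 0.080 with the library score as covariate (0.387; range over the camera alternatives 0.0766 to 0.961). JUNB, an AP-1 subunit, had a log2 fold change of 1.44 (SE 0.43) and CEBPD, a C/EBP factor, of -1.11 (SE 0.41). Integrated stress response genes had a median of 0.22 over 15 members (camera adjusted p = 0.973), with PSAT1 at -0.62 and XBP1 at -0.51. Ribosomal protein genes had a median of -0.05 over 29 members (camera adjusted p = 0.837), with RPL18 at 1.07 and RPL8 at 0.87. Of these 29 members, 0 lay above and 8 below in both knockout libraries. The percentiles of the stress response and ribosomal lists among random lists of equal expression were 98.5 and 99.9. They became 94.3 and 77.9 when the random lists were also matched on chromosome. Ribosomal genes had a median of 0.42 without the scramble library of 46.3 M tags (camera adjusted p = 0.0473), -0.40 without that of 30.4 M (0.00689), 0.12 without KO1 (0.665) and 0.20 under quantile normalization (0.0370; range over the camera alternatives 0.00500 to 0.961). Stress response genes had medians of 0.52 and -0.36 without these scramble libraries and -0.0080 without KO3, and did not pass.

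The remaining 12 tested lists did not pass with all 4 libraries and no covariate. In the list of KDM5 family and H3K4 methylation enzymes (camera adjusted p = 0.504), the methyltransferase subunits SETD1B and KMT2D had log2 fold changes of 1.25 and 1.07. Among myeloid maturation receptors (0.252), the integrins ITGB2 and ITGAX had 1.01 each. Among progenitor genes (0.837), GATA2 had 0.94 and IGFBP7 -0.72, and among cell cycle and DNA replication genes (0.660), the helicase subunits MCM2 and MCM5 had 0.89 and 0.86. The cell cycle and DNA replication list had a median of -0.17, with 4 of 30 members above and 8 below in both knockout libraries. In the interferon response list (0.837), IRF7 had 1.66 and ISG15 1.32, both past the threshold adjusted over the list alone. Their scramble means of 4.26 and 3.63 lay near the minimum of 3.32 for testing. The interferon list as a whole had a median of -0.10 over 20 members, at percentile 10.8 of random lists of equal expression. In both knockout libraries 4 of its members lay above and 1 below. Among immediate early and heat shock genes (0.245), ZFP36 had 0.82 beside JUNB, and among mitochondrial respiratory chain genes (0.793), COX8A had 1.10 and NDUFA13 0.96. The mitochondrial list had a median of -0.07, with 0 of 27 members above and 10 below in both knockout libraries. Apoptosis genes (0.878) held BIRC3 at -0.54 and FAS at -0.67, cell cycle inhibitors (0.915) CDKN2D at 0.86 and GADD45B at 0.58, and inflammatory genes (0.837) IL1RN at 0.48 and CSF1 at 0.38. Of the lists for other cell types, monocyte and macrophage markers (0.878) held LGALS3 at 0.50 and MS4A7 at -0.43, and lymphoid markers (0.205) NKG7 at 0.75 and CD79A at 0.70. Erythroid and megakaryocyte markers had 4 tested members each and MHC class II genes 0, too few for a test, with TFRC at -0.34, ANK1 at 0.90, ITGA2B at 0.49 and GP1BB at 0.91, which was past the threshold adjusted over the list alone. Of these lists, 3 passed camera in some alternatives. Mitochondrial genes had a median of -0.36 without the scramble library of 30.4 M tags (adjusted p = 0.00198) and -0.39 with the library score as covariate (5.63e-06; range 5.63e-06 to 0.961), but 0.22 without the scramble library of 46.3 M tags (0.469). Lymphoid markers had a median of 0.88 without the scramble library of 46.3 M tags (adjusted p = 0.0204) and 0.57 without KO3 (0.0235; range 0.0204 to 0.961), but -0.18 without the scramble library of 30.4 M tags (0.490). Maturation receptors had a median of 0.45 without KO3 (adjusted p = 0.0235; range 0.0235 to 0.961). No member of these lists passed over all genes, with limma adjusted p from 0.258 for IRF7 to 0.885 for TFRC among those named, and the camera direction was opposite to the sign of the median in the KDM5 family, interferon, ribosomal, stress response, apoptosis and cell cycle inhibitor lists.

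**Figure D3:**
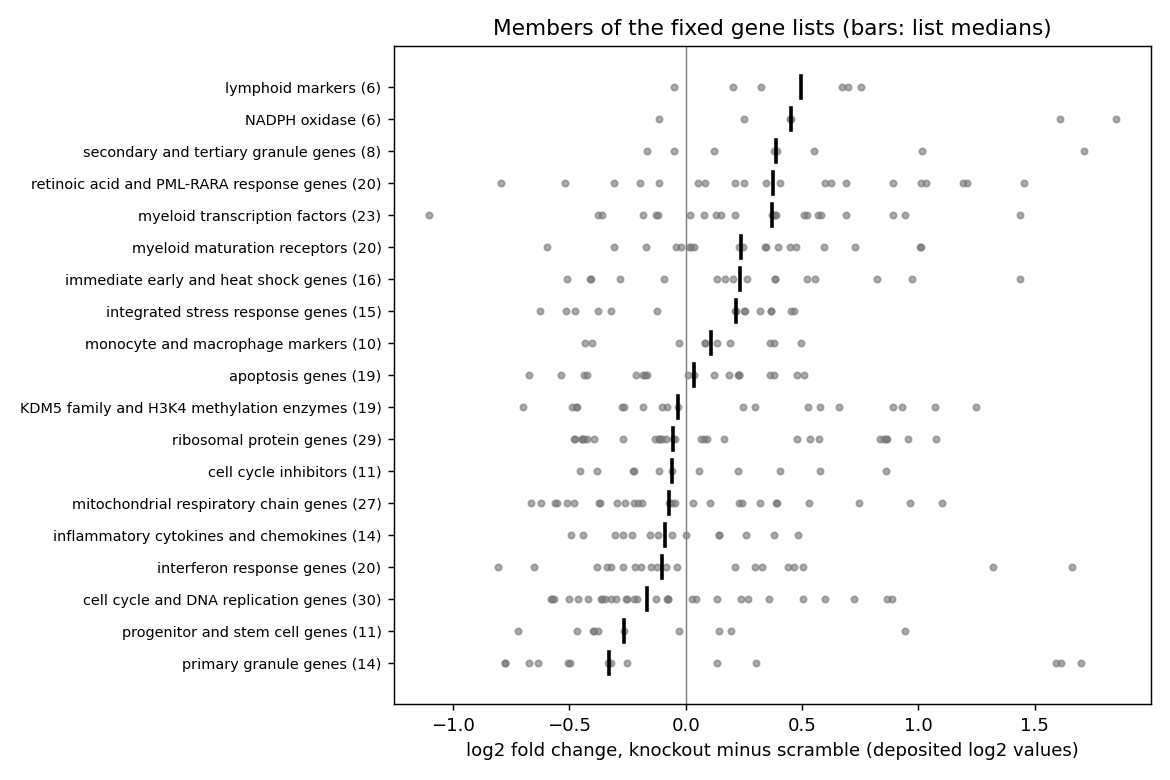
Log2 fold change (knockout minus scramble, deposited log2 values) of each tested member of 19 gene lists, 1 point per gene, with a bar at the list median and the number of members in parentheses. NADPH oxidase and retinoic acid response genes have medians of 0.45 and 0.37, and primary granule genes of -0.33 with 3 members near 1.6.

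KDM5A occupied promoters. Of 1947 KDM5A peaks in wild-type cells, 1821 (93.5%, 95% interval 92.3 to 94.6) lay within 1 kb of a TSS, at 2430 genes. Strong peaks lay at NAGPA (chromosome 16, 5083210 to 5084165, fold 83.3), which encodes an enzyme of lysosomal sorting, and at the TCA cycle subunit IDH3B (chromosome 20, 2644136 to 2645042, fold 83.0). Further strong peaks were at SFSWAP (chromosome 12, 132195271 to 132196042, fold 81.2) and NGDN (chromosome 14, 23938730 to 23939407, fold 76.2). Each of these spanned the TSS of the gene and overlapped a scramble H3K4me3 peak, and NGDN had no H3K4me2 peak in either condition there. KDM5A also had a peak at its own TSS. H3K4me3 peaks met 98.6% (95% interval 98.0 to 99.1) of KDM5A peaks in scramble and 98.7% (98.0 to 99.1) in knockout, and H3K4me2 peaks met 66.6% (64.5 to 68.7) and 78.5% (76.6 to 80.3). When 50% of the KDM5A peak had to overlap, H3K4me2 peaks met 29.0% and 45.5%.

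More H3K4me2 peaks were listed in the knockout than in the scramble library, with 53764 against 43056 (ratio 1.25), and they covered 27.2 Mb against 20.4 Mb. Of the scramble peaks 78.02% met a knockout peak, while 57.7% of the knockout peaks met a scramble peak. These shares were 46.9% and 37.6% when 50% of both peaks had to overlap, and 89.8% and 77.4% for peaks within 1 kb. Of the 22741 peaks in the knockout library alone, 56.0% lay over 5 kb from any TSS and 17.6% within 1 kb, against 58.5% and 18.6% of the 9464 peaks in the scramble library alone. A TSS peak was present in both conditions at 11878 genes, in knockout alone at 947 and in scramble alone at 343. With the same number of strongest peaks taken from each list, 73.0% of scramble peaks and 65.8% of knockout peaks met a peak of the other list, and 750 and 525 genes had a TSS peak in knockout or scramble alone.

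H3K4me3 peaks numbered 25742 in scramble and 25286 in knockout (ratio 0.982) and covered 23.3 and 22.6 Mb. Of the scramble peaks 82.7% met a knockout peak, and of the knockout peaks 85.3% met a scramble peak. A TSS peak was present in both conditions at 12388 genes, in knockout alone at 131 and in scramble alone at 190. These ratios compare single libraries.

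**Figure D4:**
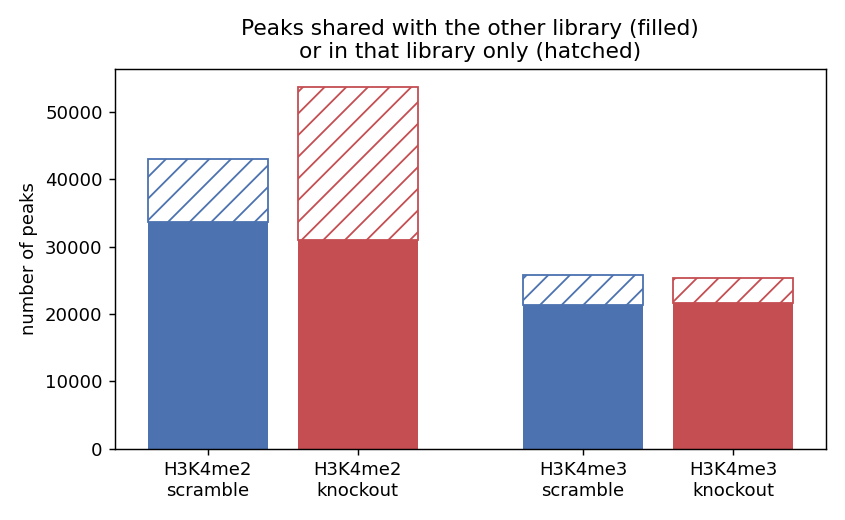
Number of H3K4me2 and H3K4me3 peaks in the scramble and knockout libraries, split into peaks that overlap a peak of the other library (filled) and peaks of that library alone (hatched). H3K4me2 has 22741 hatched peaks in knockout against 9464 in scramble, and H3K4me3 3707 against 4463.

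The deposited list of H3K4me2 regions in knockout over scramble, called gained regions here, held 4989 regions over 7.88 Mb. Among those within 5 kb of a TSS, the regions of highest fold lay near PGPEP1L (chromosome 15, 99551487 to 99552165, fold 41.9) and SHISAL1 (chromosome 22, 44710427 to 44710820, fold 38.4). Next came CCIN (chromosome 9, 36166281 to 36166673, fold 34.9), a testis gene of the sperm head. Regions of fold 30 lay beside CDC42EP1 (chromosome 22, 37952682 to 37953080 and 37957494 to 37957999), beside the non-coding LOC101928697 (chromosome 13, 19759541 to 19759906) and 683 bp from the TSS of the stem cell factor SOX2 (chromosome 3, 181430395 to 181430902). The last of these 10 lay at INTS4P2 (chromosome 7, 65112341 to 65112717, fold 27.9), MIR6071 (chromosome 2, 86006885 to 86007269, fold 26.2) and over the TSS of the connexin gene GJB6 (chromosome 13, 20805123 to 20805839, fold 25.6). All 10 overlapped a knockout H3K4me2 peak and none a scramble one, and of their 9 genes INTS4P2 alone was expressed highly enough to be tested in the RNA. Over the whole list, 97.3% of regions met a knockout H3K4me2 peak, 64.4% (95% interval 63.0 to 65.7) a scramble one, and 64.8% a scramble H3K4me3 peak, and 47.5% lay within 1 kb of a TSS against 42.8% over 5 kb away.

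Gained regions lay within 5 kb of the TSS of several myeloid regulators, but they were not more frequent in every myeloid list. Among myeloid transcription factors with a knockout H3K4me2 peak near the TSS, 11 of 29 had one (37.9% against 24.3% of all such genes; Fisher's exact test p = 0.126, adjusted p = 0.991), among them BCL6, CEBPB, CEBPD, JUNB, KLF4, KLF6, NFE2 and SPI1. Of the retinoic acid and PML-RARA list, 4 of 27 had one (CEBPB, PRAM1, RARRES3 and SPI1; Fisher's exact test p = 0.368, adjusted p = 1.0), and of secondary and tertiary granule genes 4 of 10 (CAMP, LRG1, MMP9 and SLPI; Fisher's exact test p = 0.270, adjusted p = 0.991). The region at the secondary granule gene CAMP (chromosome 3, 48264237 to 48265397, fold 9.73) had no scramble H3K4me2 or H3K4me3 peak, while that at PRAM1 (chromosome 19, 8562035 to 8569734, fold 6.5) had both. The share of the retinoic acid list, 14.8%, was below that of all such genes. Of myeloid maturation receptors 1 of 17 had a gained region (5.88%, Fisher's exact test p = 0.0909, adjusted p = 0.991). Within 1 kb it was 0 of 16 of these receptors (Fisher's exact test p = 0.0314, adjusted p = 0.690). None of the 22 lists passed this test, at either 5 kb or 1 kb.

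Gained regions had no link of constant direction to KDM5A peaks, and at TSSs, where most KDM5A peaks lie, the odds ratio was below 1. Of knockout H3K4me2 peaks that overlap a KDM5A peak, 16.5% met a gained region, against 14.5% of the others (odds ratio 1.16, 95% interval 1.02 to 1.32; Fisher's exact test p = 0.0223). Among peaks within 1 kb of a TSS the odds ratio was 0.856 (0.750 to 0.978, Fisher's exact test p = 0.0227). These held 283 of the 303 gained and 1453 of the 1536 other peaks with KDM5A. Among peaks over 5 kb from any TSS the odds ratio was 1.89 (1.09 to 3.29, Fisher's exact test p = 0.0339), resting on 16 gained and 58 other peaks with KDM5A. Over the merged H3K4me2 peaks of both libraries it was 1.25 (1.11 to 1.42; exact p = 0.000475). Within strata of knockout peak width, which a gain of the mark can itself widen, the Mantel-Haenszel odds ratio was 0.817 (0.719 to 0.929), and with KDM5A peaks within 1 kb the odds ratio was 0.975 (0.889 to 1.07). By gene, 19.8% of 2362 genes with a KDM5A peak at the TSS and 25.2% of 12138 others had a gained region (odds ratio 0.732, 0.657 to 0.817). In the gained list as a whole, 5.61% of regions met a KDM5A peak.

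**Figure D5:**
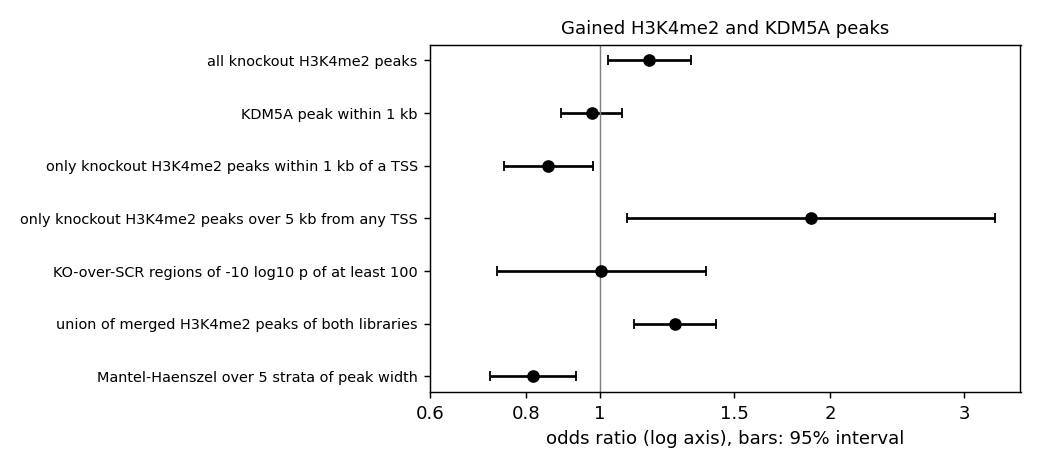
Odds ratios (log axis) of meeting a gained H3K4me2 region for peaks with against without a KDM5A peak, under each choice of background or overlap, with 95% intervals as bars. The value is 1.16 over all knockout H3K4me2 peaks, 1.25 over the merged peaks of both libraries and 0.817 at equal knockout peak width.

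Genes near gained H3K4me2 regions had higher RNA in knockout than other genes by camera with its preset correlation, but not with an estimated correlation (adjusted p = 0.715 with an estimated correlation). The 2729 tested genes with a gained region within 5 kb of the TSS had a median log2 fold change of 0.06 against -0.08 for other genes (camera adjusted p = 0.00933), above that of all 10000 random lists of equal expression (permutation p = 0.0002, the smallest these lists can give). An unadjusted p under 0.05 with higher RNA was found for 9.38% of them and 5.32% of other genes, an odds ratio of 1.84, and 0 were called. The camera call was also lost without the scramble library of 30.4 M tags (adjusted p = 0.127), with the library score as covariate (0.136) and with the stronger regions alone (0.655), within a range of 0.000205 to 0.715 over the camera alternatives. Fry, against no change, gave an adjusted p of 0.731. The difference of the medians was 0.15, against 0.27 without the scramble library of 46.3 M tags, 0.05 without that of 30.4 M, 0.093 without KO1, 0.05 without a filter, 0.04 with the covariate and 0.01 for the stronger regions.

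Genes with a KDM5A peak at the TSS did not pass camera and had a lower median than other genes. Over 2282 tested genes it was -0.14 against -0.04 (camera adjusted p = 0.0676, and 0.715 with an estimated correlation), at percentile 0.04 of random lists of equal expression (random-list p = 0.001). The median of those random lists was -0.112, so other genes of equal expression were lower as well, and the difference from them was -0.031. The set passed camera without a filter (adjusted p = 0.0193), with the library score as covariate (0.0333), without the scramble library of 30.4 M tags (0.00818) and without KO3 (0.0371), within a range of 0.00818 to 0.715 over the camera alternatives. The difference of -0.11 from all other genes shrank to -0.03 under quantile normalization (adjusted p = 0.581), -0.04 without KO1 (0.325) and -0.06 at a minimum mean of 7 (0.162), and the set did not pass without the scramble library of 46.3 M tags (0.390) either. For the 426 tested genes with both a KDM5A peak and a gained region the median was 0.03 against -0.06 (camera adjusted p = 0.110), above all 10000 random lists (permutation p = 0.0002), and the set passed camera without the scramble library of 46.3 M tags (adjusted p = 0.0242) and lay below other genes without that of 30.4 M (0.781), within a range of 0.00830 to 0.945. Its difference of 0.09 fell to 0.02 without a filter (0.282), -0.02 with the covariate (0.945) and -0.05 for stronger peaks (0.452). MT2A had neither a KDM5A peak nor a gained region, and 0 genes were called in either set.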

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

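Median centring, quantile normalization, no trend, array weights, a minimum mean of 7, the library score as covariate, lists matched on chromosome and the minimum score of gained regions were chosen only after the data had been seen. No paired analysis was possible because the scramble columns carry no replicate number and 1 knockout column bears a number that no title has. The alternatives with count tools were not run because the values are not counts, treating duplicate symbols separately changed nothing because there were none, and a q minimum for gained regions could not be applied because that list gives no q. KDM5A expression kept its direction and stayed short of the threshold in all 12 alternatives, and MT2A kept its direction in 12 and lost its call in 3.

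Against 1 called gene, the count was 0 without a filter, 3 at a mean of 1 CPM, 8 at a minimum mean of 7, 88 with median centring, 0 without a trend, 3 with array weights and 6 with the covariate, and from 0 to 1260 when 1 library was left out. The 2 passing lists became 0 without a filter, at a mean of 7 (where NADPH oxidase, with 4 members left, was not tested), with an estimated correlation and with fry, which asks another question, 3 with the covariate, of which none was among the 2, and 0 to 5 when 1 library was left out. List medians changed sign with the covariate for NADPH oxidase (-0.0088), stress response (-0.33), lymphoid (-0.19), monocyte (-0.17) and immediate early (-0.037) genes. They also did so with it for KDM5 family (0.078), interferon (0.013), cell cycle inhibitor (0.11) and apoptosis (-0.042) genes. With quantile normalization they changed sign for ribosomal (0.20), KDM5 family (0.12) and monocyte (-0.045) genes. Leaving out 1 library moved primary granule genes from -0.77 to 0.19, ribosomal genes from -0.40 to 0.42 and stress response genes from -0.36 to 0.52. A library left alone in its group was assumed to vary like the other group. The median difference of genes with a KDM5A peak passed without a filter (-0.12), with the covariate (-0.094) and against matched lists (-0.031 on expression, -0.045 with chromosome), was -0.032 under quantile normalization, and ran from -0.163 to -0.042 when 1 library was left out. That of genes near gained regions was 0.145 with an estimated correlation, 0.038 with the covariate and 0.014 for stronger regions, where camera did not pass, and from 0.052 to 0.267 when 1 library was left out. For genes with both it passed with quantile normalization (0.143) and against matched lists (0.151 and 0.112), changed sign with the covariate (-0.018) and for stronger peaks (-0.054), and ran from -0.026 to 0.243 when 1 library was left out. Peak number ratios were 1.32 at a −log10 q of 5 and 1.21 at a fold of 5 for H3K4me2, and 0.919 and 0.933 for H3K4me3. When 50% of the KDM5A peak had to overlap, the share on scramble H3K4me3 was 93.5% and those on H3K4me2 fell to 29.0% in scramble and 45.5% in knockout. The odds ratio of gained regions against KDM5A was 0.975 within 1 kb, 0.856 at TSS peaks, 1.004 at a minimum score of 100 and 0.817 at equal width of knockout peaks, while it stayed above 1 over merged peaks (1.25) and over 5 kb from a TSS (1.89). The cause was not tested, except that fewer libraries or genes enter where they are left out. The settings of no trend and array weights were not passed to camera, so they and fry are left out of these tallies for gene sets. Among all other alternative values of the results that answer a comparison, 55 kept direction and side of the threshold or moved little, 23 moved, 10 newly passed, 5 no longer passed and 6 changed sign. For single genes, shares and some of the lists these numbers were 76, 38, 6, 13 and 8. The newly passing values of the first tally include random-list p-values, for genes with a KDM5A peak and for genes with both. A random-list p carries no spread between libraries. The lists counted were both granule lists, NADPH oxidase, myeloid transcription factors, retinoic acid response, ribosomal and stress response genes. The other tested lists are not in this tally, although some of them passed camera or changed sign in alternatives. Depth limits KO1 most, at 5.53 M tags.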

Other observations

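The tests of the library axis, of library depth, of gained regions with a scramble peak and of lists against KDM5A peaks were chosen only after the result was seen, as were the odds ratios at a minimum score of 100 and by gene and the use of the otherwise planned odds ratios to weigh a cause, while the tests of base composition and of RNA at KDM5A peaks were not.

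KDM5A peaks were counted in each gene list, and no list passed the adjustment over 22 lists. Among mitochondrial respiratory chain genes with a scramble H3K4me3 peak at the TSS, 11 of 26 had a KDM5A peak (42.3% against 19.3% of all such genes; Fisher's exact test p = 0.00971, adjusted p = 0.107), among them the complex I subunits NDUFA2, NDUFA9, NDUFB3, NDUFB5, NDUFS3 and NDUFV1 and the succinate dehydrogenase subunits SDHB and SDHC. Of ribosomal protein genes 9 of 29 had one (Fisher's exact test p = 0.152, adjusted p = 0.372). Of interferon response genes 0 of 24 had one (Fisher's exact test p = 0.00859, adjusted p = 0.107) and of retinoic acid and PML-RARA response genes 0 of 20 (Fisher's exact test p = 0.0215, adjusted p = 0.158). Of 27 myeloid transcription factors with such an H3K4me3 peak, GFI1B alone had a KDM5A peak (Fisher's exact test p = 0.0468, adjusted p = 0.206).

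Tested relatives of MT2A did not pass. MT1X and MT1F, tested neighbours on chromosome 16 looked up after MT2A had been seen, had log2 fold changes of 0.84 (SE 0.51) and 0.48 (SE 0.41) and overlapping groups, with limma adjusted p = 0.871 and 0.874. HMOX1, a heme oxygenase that responds to metals and oxidants, had 0.37 (SE 0.29, limma adjusted p = 0.874), and the zinc exporter SLC30A1 0.21 (SE 0.44, limma adjusted p = 0.922). Reads shared between metallothionein copies were not tested.

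Of the genes with an unadjusted p under 0.05, 793 were higher in knockout and 70 lower, with 390 of the higher ones on chromosomes 16, 17, 19, 20 and 22, but 300 and 137 with the library score as covariate and 214 and 101 without the scramble library of 30.4 M tags. Against loss of KDM5A at its own sites as their whole source, the median of genes with a KDM5A peak lay at percentile 0.04 of matched random lists. That median differed from the median of the matched lists by -0.031 only. Derepression would place it high. The set did not pass camera after adjustment, however (camera p = 0.0450 unadjusted, adjusted p = 0.0676, and 0.715 with an estimated correlation). Its difference shrank from -0.107 to -0.032 under quantile normalization and -0.042 without KO1. The 426 genes that also had a gained region lay above all matched lists. The difference between the scramble libraries and that between the knockout libraries, which share no library, correlated across genes (Spearman rho 0.470; genes are not independent replicates), so an axis of library quality or composition may underlie part of the pattern. The median log2 fold change of chromosomes 16, 17, 19, 20 and 22 exceeded that of chromosomes 3, 4, 5, 6, 13, 18 and X by 0.435 (bootstrap 95% interval 0.411 to 0.471). That interval carries no spread between libraries. The scramble libraries alone differed by medians of 0.502 and -0.134 on these chromosome groups. Base composition is therefore a candidate explanation. An indirect effect of the knockout stays open and was not tested.

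The knockout H3K4me2 library had more peaks and covered length. A deeper knockout library is argued against by the background rate of the peak caller, 0.20 in knockout and 0.279 in scramble (ratio 0.716), with a shortest peak of 200 bp in both lists, if both were called against the same control. Of the 4989 gained regions, 5.61% met a KDM5A peak. The 1947 called KDM5A peaks are fewer than the regions, so a low share was set by the sizes of the lists. It therefore cannot weigh loss of KDM5A at its sites as a source of the gain, and that source stays open. The odds ratio of meeting a gained region at KDM5A peaks was 1.16 over all knockout peaks and 1.25 over merged peaks. At TSS peaks, which held 283 of the 303 gained and 1453 of the 1536 other peaks with KDM5A, it was 0.856. Over 5 kb from a TSS it was 1.89, on 16 gained and 58 other peaks. The odds ratio was 1.004 at a minimum score of 100, 0.975 within 1 kb and 0.732 by gene. Within strata of knockout peak width it was 0.817 (95% interval 0.719 to 0.929), and whether a gain of the mark alters these widths was not tested. A better immunoprecipitation cannot be told apart from a gain of the mark, because 64.4% of gained regions had a scramble peak and there is 1 library per condition.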
